A study of Homo sapiens with 8 samples.

How the data were processed

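RNA of NALM6 cells was measured by SLAM-seq in 8 libraries, 3 of the wild-type HMGN1 line with vehicle, 3 of the same line with doxycycline and 2 of the S20,24E mutant line with doxycycline. Groups and replicate letters were taken from the labels. Per the labels, libraries were made with a stranded mRNA kit and sequenced on a NextSeq 500. Per the submitters' processing notes the genome build was hg19 (GRCh37). The aligner, the conversion caller, their versions, the counted region and the use of strand in counting are not given in the sources used here.

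The deposited all-read columns, named CPM per the file headers, were treated as a signal per RefSeq transcript whose column sums exceed a whole library, because transcripts of a gene repeat the same reads. In each library every value was a whole multiple of a single step, so that 100.0% of values were whole read counts within 0.1 read. The conversion columns, named CONVERSION per the file headers, were treated as a conversion rate per transcript, as a fraction, which is also 0 where no read was counted. The headers do not say whether bases or reads are meant. The converted-read values were deposited as FPKM per transcript. In that FPKM table the low values of a library lay near whole multiples of a step (0.175 to 0.524 by library, 93.3% to 99.0% of low values), with no trace of division by transcript length, and they were used as deposited.

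The all-read table had 61177 rows for 58365 accessions. A symbol was missing for 25396 rows, of which 24846 were named through the RefSeq gene table of GRCh38.p14, used for names only, and 60133 rows matched that table. Transcripts were assigned to 27424 genes, of which 503 kept only an accession. In each table a gene took the values of its transcript row with the highest mean, and its other rows were left out. The converted table had 10032 rows for 6993 genes, with 261 rows at 0 in all libraries. In all reads, 38 of 38 transcript pairs with the same span, exon lengths over 300 bases apart and a mean of at least 20 CPM had identical values. In converted reads, 96 of 102 single-exon transcripts were at 0 in all libraries, against 56 of 8374 with several exons. Exon structures for these checks, available for 8476 converted transcripts, and pseudogene sequences came from GENCODE 29, joined by accession, and no coordinates of that build were used with the files. Overlapping genes, antisense partners and near-identical copies cannot be told apart in these tables.

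A count model with edgeR had been planned before the data were examined. The deposited units are not counts, and limma 3.58.1 (R 4.3.3) on the log2 scale was used in its place. Values of a gene were tested as log2(value + 1) where the mean was at least 1, with all 8 libraries in a single model and no covariate, so that a fold change of a low gene is understated. New RNA, chosen after seeing the data, is CPM multiplied by the conversion rate as a fraction per gene, tested as log2(value + 0.1) where the mean was at least 0.2, with each library's median set to 0. The planned interaction test of the converted share in edgeR could not be run, as no converted counts were used here. On the recovered reads, edgeR 4.0.16 (quasi-likelihood, TMM scaling) and DESeq2 1.42.0 (Wald test) were added as alternatives. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, passing below 0.05. Summed FPKM, the converted share (the conversion rate averaged over gene reads) and the HMGN1 values were compared with exact two-sided permutation tests in R. The smallest p of this test is 0.1 for 3 against 3 and for 3 against 2 libraries. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

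For gene groups, 31 lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, which left 21 lists in converted reads, 25 in all reads and 24 in new RNA. They cover B-cell and other lineage markers, chromatin and transcription proteins, the cell cycle, stress and signalling responses, ribosomes, mitochondria, glycolysis, cholesterol synthesis, apoptosis and housekeeping genes. Camera was rerun with an estimated correlation, and fry asked whether a list moved one way. The rule for named genes, also fixed before the data were examined, took HMGN1, then per comparison the 10 largest rises and 10 largest falls among genes that passed and whose libraries did not overlap between groups. If fewer than 5 passed, it took the 5 with the smallest p in each direction. It further took up to 4 members with the smallest p of each described list and the 10 most abundant converted genes with vehicle. MAD1L1, the all-read folds of converted-read genes, and PPEF2, C11orf67, UNC45B and SLCO5A1 per library were chosen after their values were seen. Some genes that the rule takes are not reported here.

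The depth, in M reads, was 8.89, 11.5 and 17.7 for vehicle A, B and C, 14.4, 7.99 and 13.8 for induced wild type A, B and C, and 10.4 and 11.6 for induced mutant A and B. Each test was tried on simulated data with 100 genes changed by 2-fold and 100 by 4-fold, in a single draw per comparison, of which 97 to 99 per fold were tested with edgeR and DESeq2. In converted reads (5737 genes) limma recovered 17% of the 2-fold and 91% of the 4-fold changes for induced wild type against vehicle with 9 false calls, 6% and 75% for induced mutant against vehicle with 3, and 10% and 78% between the induced groups with 2. In all reads (12458 genes) it recovered 62% and 99%, 33% and 95%, and 35% and 99% in the same order, with 7 false calls each. In new RNA (9653 genes) it recovered 77% and 100%, 58% and 100%, and 55% and 100%, with 10, 9 and 8 false calls. With edgeR (13192, 13183 and 13210 genes) the shares were 40.4% and 94.9%, 38.4% and 91.9%, and 29.9% and 88.8%, with 8, 11 and 7 false calls. With DESeq2 on the same genes they were 48.5% and 92.9%, 49.5% and 93.9%, and 36.1% and 87.8%, with 19, 27 and 18 false calls. A 2-fold change of a single gene was thus mostly not detected in simulated converted reads. In the list test, simulated for induced wild type against vehicle over 21 lists, 3 of 3 shifted lists were found with the preset correlation and with fry and 2 of 3 with the estimated correlation, with 0 others called. All simulated genes were drawn independently of each other, so recovery and false calls do not reflect correlation between genes in the real libraries.

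The alternatives covered normalization, filters, pseudocounts, the libraries in the fit, the replicate letter as a block, log2 depth as a covariate, leaving out each library in turn, the other table and, for the summed level, the median over genes and the sum without the 50 most abundant genes. Where a group was left with 1 library, that library was assumed to vary like those of the other groups. No spike-in and no mitochondrially encoded rows were found, so those settings could not be run.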

Results

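NALM6 is an established human line of precursor B-cell acute lymphoblastic leukaemia. In these cells a doxycycline-inducible HMGN1 gene was either wild type or a mutant, S20,24E, that binds nucleosomes poorly, and HMGN1 itself is a small nucleosome-binding chromatin protein encoded in the Down syndrome critical region. Cells received 100 ng/ml doxycycline or vehicle for 6 h, and 4-thiouridine at 100 µM was present for the last 5 h, so that RNA made in that time carried the label. In SLAM-seq the label is read as T-to-C conversions after thiol modification, here from 4 µg of total RNA. There were 3 libraries of the wild-type line with vehicle (vehicle), 3 of the wild-type line with doxycycline (induced wild type) and 2 of the mutant line with doxycycline (induced mutant), described as biological replicates A to C. Vehicle-treated cells of the mutant line were not analysed here. Converted reads were taken per transcript from the deposited FPKM table, all reads per transcript from the CPM columns, and new RNA is CPM multiplied by the conversion rate. The depth behind the CPM values ran from 7.99 M reads (induced wild type B) to 17.7 M (vehicle C), of which 3.43 M to 7.85 M lay in gene rows. The p-values below measure the spread between these replicate libraries, which the labels call biological without saying whether they came from separate cultures.

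The first question was whether the induced gene was higher in the induced libraries. In all reads HMGN1 stood at 163 ± 24.4 CPM (SD, n = 3) with vehicle, 262 ± 51.0 (n = 3) in induced wild type and 211 ± 16.7 (n = 2) in induced mutant. Its conversion rate was 1.47% ± 0.37 with vehicle, 4.82% ± 2.04 in induced wild type and 3.32% ± 1.87 in induced mutant. HMGN1 new RNA rose in induced wild type to 13.3 ± 8.21 from 2.33 ± 0.305 with vehicle, a log2 fold change of 2.04 (SE 0.28, limma adjusted p = 0.0403), and was 7.17 ± 4.51 in induced mutant (1.38, adjusted p = 0.165). The conversion rate was higher in every induced library than in every vehicle library (exact two-sided permutation p = 0.1 in both comparisons, the smallest that 3 against 3 or 2 against 3 libraries can give). In all reads the exact p for HMGN1 was 0.1 for induced wild type against vehicle and 0.2 for induced mutant against vehicle. By limma HMGN1 did not pass in all reads in either comparison. Its log2 fold change for induced mutant was 0.38 (limma adjusted p = 0.9999). For induced wild type it was 0.67 with the replicate letter as a block (limma adjusted p = 0.991), and no gene passed without the block. In the converted-read table HMGN1 did not differ detectably, at 4.71 ± 1.81 FPKM with vehicle, 6.03 ± 1.51 in induced wild type and 3.39 ± 1.08 in induced mutant. Induced wild type and induced mutant were not told apart in HMGN1 new RNA (exact p = 0.6). The new RNA call for HMGN1 was lost without any one of the 6 wild-type-line libraries, with adjusted p of 0.0751, 0.308 and 0.313 without vehicle A, B and C, and 0.192, 0.106 and 0.0912 without induced wild type A, B and C. It was also lost when new RNA was not median-centred (0.343) or was filtered at a mean of 1 (0.108), and HMGN1 reads are uncertain because the annotation holds 31 processed HMGN1 pseudogenes.

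**Figure D1:**
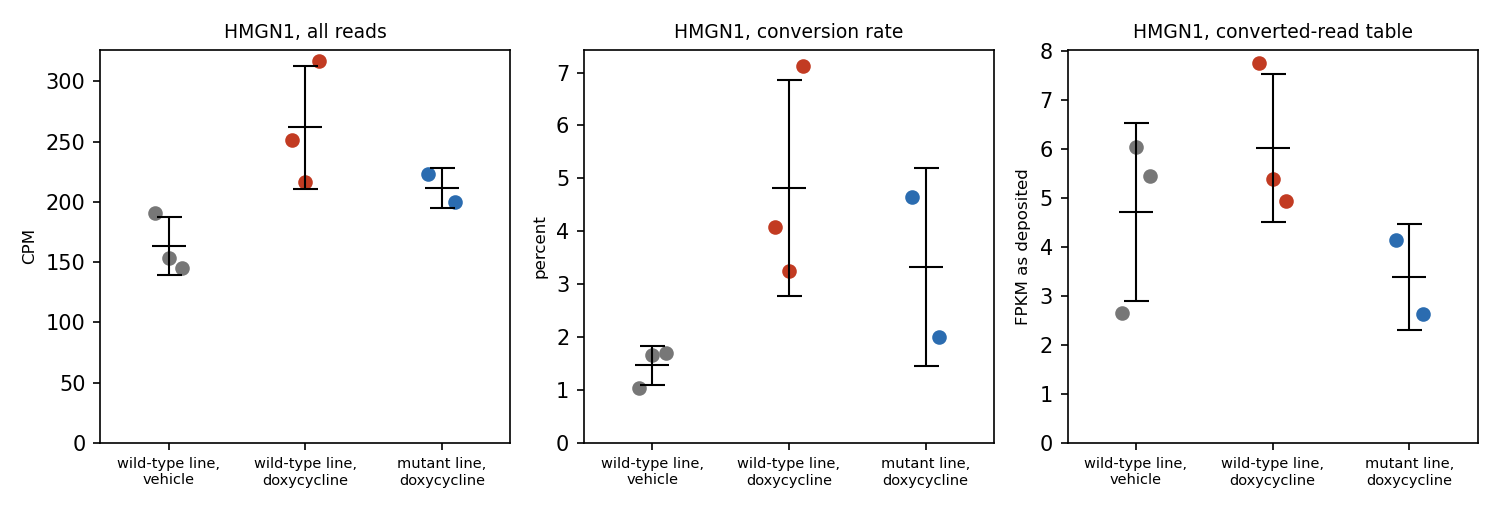
HMGN1 per library in all reads (CPM), as conversion rate (percent) and in the converted-read table (FPKM), with points for libraries, and bars for the mean and SD of the vehicle (n = 3), induced wild-type (n = 3) and induced mutant (n = 2) groups. The conversion rate averaged 1.47% with vehicle and 4.82% and 3.32% in the induced groups, while the converted-read values of the vehicle group overlapped those of both induced groups, which did not overlap each other.

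The next question, raised by the subject of the series, was whether induction raised RNA production across the genome. The converted-read values, summed over the kept transcript row of each gene, came to 32701 ± 3970 FPKM with vehicle, 38557 ± 5364 in induced wild type and 39752 ± 5860 in induced mutant. The ratio to vehicle was 1.18 for induced wild type (exact p = 0.2) and 1.22 for induced mutant (exact p = 0.3), and 0.97 between the induced groups (exact p = 0.9). FPKM values are scaled within each library and no spike-in rows were found, so these sums can neither show nor exclude a change in total RNA production. The converted share over all gene reads was 3.60% ± 0.93 with vehicle, 4.32% ± 0.91 in induced wild type and 4.03% ± 0.87 in induced mutant, with exact p of 0.5, 0.6 and 0.8 in the 3 comparisons. None of these differences passed the exact test, whose smallest two-sided p is 0.1 in this design. The differences in sums from vehicle were larger than the SD of either group, while those in converted share, and that in sums between the induced groups, were smaller. Vehicle A held the lowest sum, 28206 FPKM, and the lowest converted share, 2.64%. Without vehicle A the difference in converted share between induced wild type and vehicle was 0.23 percentage points instead of 0.71. Without induced wild type C the log2 difference in sums was 0.12 instead of 0.24. For induced mutant against vehicle, leaving out mutant A turned the difference in converted share from 0.42 to -0.19 percentage points and left a log2 difference in sums of 0.13 instead of 0.28, and leaving out vehicle A gave a share difference of -0.06. Without mutant B the share difference of this comparison was 1.04 percentage points, and without induced wild type B that of induced wild type against vehicle was 1.18 and without vehicle C 1.16.

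Induced wild type was compared with vehicle in the same line to ask which genes respond to wild-type HMGN1. Doxycycline also differs between these groups, so a response to doxycycline and a response to HMGN1 cannot be told apart here. In converted reads no gene passed, and the following are among those with the smallest p in each direction. SH2B3, an adaptor that restrains cytokine signalling, stood at 5.93 ± 1.68 against 1.46 ± 0.877 FPKM (log2 fold change 1.53, SE 0.37, n = 3 and 3, limma adjusted p = 0.478). ARID3A, a B-cell DNA-binding factor, had a log2 fold change of 1.78 and ARFGEF2, an exchange factor for ARF GTPases, of 1.94 (adjusted p = 0.478 each). MECOM, a zinc finger transcription factor, was listed at 0 in all 3 vehicle libraries and at 4.89, 5.85 and 2.87 FPKM in induced wild type A, B and C (adjusted p = 0.478). It was also at 0 in mutant A, and in all reads its log2 fold change was -0.10 (adjusted p = 0.992). The falls with the smallest p were in MAGI1, a junctional scaffold (-1.41), the protocadherin PCDH11Y (-1.50), the creatine-synthesis enzyme GAMT (-1.09), the depalmitoylase ABHD17B (-0.94) and ARL6IP4 (-0.67), with adjusted p from 0.536 to 0.590. Of the precursor B-cell genes, the transcription factors PAX5 (1.18), FOXO1 (0.89) and EBF1 (0.78) leaned higher without passing, and the list of 25 tested members did not pass (adjusted p = 0.735). Ribosomal protein genes fell relative to other genes, with a median of -0.10 over 33 members, 21 of them below 0, while the median of all genes was 0.23 (camera adjusted p = 3.03e-04, and 0.156 with an estimated correlation). Median centring put the median of all genes at -0.11 and that of the ribosomal protein genes at -0.43. The call was also lost without vehicle A (0.303) and without induced wild type C (0.209), and a further list passed without induced wild type A, for 2 lists in all. Limma called 0 of 5737 genes, and 455 had an unadjusted p under the 0.05 level. Leaving out vehicle C gave 1 call, as did depth as a covariate, a setting added after seeing the data. The libraries of the groups did not overlap for 614 genes higher and 72 lower, 12.0% of those tested, where chance alone gives 10%. In all reads this held for 4.04% and in new RNA for 2.37%.

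In all reads the same comparison put C1orf14 at 70.4 ± 30.0 against 13.5 ± 0.89 CPM (log2 fold change 2.22, limma adjusted p = 0.339) and TMEM131, a membrane protein gene, at 44.7 ± 22.6 against 10.2 ± 1.82 CPM (1.93, adjusted p = 0.825). Both hold a processed HMGN1 pseudogene inside the gene, which makes their counts uncertain. The next smallest p belonged to C11orf67 (1.22), ARHGAP24 (0.80) and NRIP2 (0.86) among higher genes, and to the kinase gene MAPK11 (-0.52), the thymidine phosphorylase gene TYMP (-0.60), STRADB (-0.52), MIR4647 (-0.44) and MIR6752 (-0.44) among lower ones, none passing (adjusted p = 0.992 each). Limma called 0 of 12458 genes, with 118 at an unadjusted p under 0.05, while edgeR and DESeq2 on the recovered reads each called 2 of 13387, with 286 and 195 at that unadjusted level. In new RNA, C1orf14 rose by 4.08 on the log2 scale (7.46 ± 5.11 against 0.254 ± 0.174, limma adjusted p = 5.99e-04) and was called with HMGN1 as the only genes of 9653. Of the lists, ribosomal proteins (median -0.22, 34 of 34 below 0, adjusted p = 3.45e-16), nuclear-encoded oxidative phosphorylation (-0.16, 24 of 26, 1.32e-10), mitochondrial ribosome (-0.11, 14 of 22, 2.26e-04) and housekeeping genes (-0.07, 11 of 12, 0.0031) fell relative to a median of 0.09 for all genes. With an estimated correlation each of the 4 had an adjusted p of 0.706. Examples are RPS3 of the small ribosomal subunit (-0.38, SE 0.27), NDUFS3 of respiratory complex I (-0.30, SE 0.18) and MRPL47 of the mitochondrial ribosome (-0.23, SE 0.15), none passing alone. Leaving out induced wild type C removed all 4 calls (adjusted p 0.176, 0.0630, 0.484 and 0.176 in that order), leaving out vehicle A removed those of ribosomal proteins (0.0766), mitochondrial ribosome (0.309) and housekeeping genes (0.0766), and leaving out induced wild type B gave 7 lists. Vehicle A and induced wild type C also lay at the ends of the converted share in these groups, at 2.64% and 5.20%. In new RNA ribosomal protein genes (median -0.26, 34 of 34 below 0, adjusted p = 5.00e-04) and oxidative phosphorylation genes (-0.21, 24 of 25, 0.0033) fell, with an adjusted p of 0.958 with an estimated correlation.

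Induced mutant was compared with vehicle in the wild-type line, so that line and doxycycline differ together. In converted reads 23 of 5737 genes passed, 22 higher and 1 lower. CXXC5, a CXXC zinc finger protein gene, rose by 2.45 (log2, SE 0.46) to 14.6 ± 4.97 (n = 2) from 2.17 ± 1.99 FPKM (n = 3), with a limma adjusted p of 0.0290. SH2B3 rose by 2.44 (SE 0.42), FAM53B by 2.43 (SE 0.42), the heparan sulfate sulfotransferase gene HS6ST1 by 2.37 (SE 0.39) and the coregulator gene ZMIZ1 by 2.25 (SE 0.39), each with an adjusted p of 0.0262. ARID3A (2.36), MEGF6 (2.35), the potassium channel gene KCNJ12 (2.31) and IQSEC1, an exchange factor for ARF GTPases (2.27), rose with adjusted p from 0.0290 to 0.0414. Further rises included ANKRD30BL (2.19), MAD1L1, of the spindle checkpoint (1.38), and PAX5, which sets B-cell identity (1.79, SE 0.37, adjusted p = 0.0445). IL6R, an interleukin receptor gene, fell: it was listed at 0 in both mutant libraries and at 5.76, 4.76 and 2.63 FPKM in vehicle A, B and C (adjusted p = 0.0290). Adjusted over the list alone, 2 precursor B-cell genes rose (PAX5, and FOXO1 at 1.40), as did DOPEY2 of the Down syndrome critical region (1.55), the p53 target MDM2 (1.30) and the acetyltransferase genes KAT6B (1.69) and CREBBP (1.53), of which only PAX5 passed over all genes. None of these 4 lists passed as a whole (adjusted p of 0.875 for precursor B-cell genes, 0.847 for the Down syndrome critical region, 0.271 for p53 targets and 0.528 for acetylation genes). Ribosomal protein genes fell relative to other genes (median -0.14, 24 of 33 below 0, against 0.17 for all genes, adjusted p = 0.0062), with an adjusted p of 0.318 with an estimated correlation, 0.259 without mutant A and 0.203 without vehicle A.

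The split of these calls depended on scaling: quantile normalization gave 80 higher and 13 lower, and median centring 32 higher and 9 lower. The groups did not overlap for 1172 genes higher and 448 lower, 28.2% of those tested, where chance gives 20%. In all reads they did not overlap for 575 higher and 1423 lower of 12458 genes, and in new RNA for 8.75%. With a pseudocount of 0.1 the only call was IL6R, with the first 9 named rises at an adjusted p of 0.106 to 0.304. With only the 2 groups in the fit 2 genes were called, 1 of them shared. Those rises then had an adjusted p of 0.0530 to 0.138 and IL6R of 0.0858. With depth as a covariate 157 genes were called, among them all 23. The fold changes followed gene span across genes (Spearman rho 0.50), and 10 genes passed after each library's trend on span was removed, against 30 before on the same 5004 genes. The count became 0 without mutant A, 1 without mutant B, 35 without vehicle A, 0 without vehicle B, 68 without vehicle C and 9 without induced wild type A. Each of the first 9 named rises and IL6R lost its call without mutant A (adjusted p = 0.740), without mutant B (0.0702 to 0.198) and without vehicle B (0.0829 to 0.107). Without induced wild type A, CXXC5 (0.0603), ARID3A (0.0598), MEGF6 (0.0953), IQSEC1 (0.0502) and IL6R (0.0584) lost theirs, and MEGF6 also without induced wild type B (0.0616) and C (0.0517). In all reads none of these 10 genes passed. The largest of their changes there was in ARID3A, at 8.58 ± 2.87 against 3.20 ± 1.22 CPM. The log2 fold changes of the others were 1.04 for FAM53B and KCNJ12, 0.93 for ZMIZ1, 0.83 for SH2B3, 0.67 for IQSEC1, 0.63 for MEGF6, 0.62 for CXXC5, 0.46 for HS6ST1 and -0.05 for IL6R.

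In all reads of the same comparison 4 of 12458 genes passed. ALDOC, a glycolytic aldolase gene, fell by 1.94 (log2, SE 0.17) to 24.0 ± 3.82 (n = 2) from 94.4 ± 7.93 CPM (n = 3), with a limma adjusted p of 0.0067. COL5A1, a fibrillar collagen gene, fell by 2.19 (SE 0.29) to 1.51 ± 0.18 from 10.8 ± 3.07 CPM (adjusted p = 0.0495). LOC101448202, which overlaps it and may share its reads (not tested), fell by 2.23 (SE 0.25, adjusted p = 0.0251). MYBPC2, a myosin-binding protein gene of fast muscle, rose by 1.88 (SE 0.23) to 6.04 ± 1.83 from 0.88 ± 0.18 CPM (adjusted p = 0.0429). The next smallest p, not passing, belonged to ANKRD30BL (2.33), PPEF2 (2.08), C11orf67 (2.04) and LOC101927817 (1.22) among higher genes and to C8orf73 (-1.49) and the adenylate kinase gene AK1 (-1.25) among lower ones (adjusted p from 0.229 to 0.358). In new RNA C1orf14 (3.34), MYBPC2 (2.38), MEGF6 (1.54) and TBC1D22A (1.47) rose, with adjusted p from 0.0170 to 0.0452, while new RNA without median centring, with a pseudocount of 0.5 or with a filter at a mean of 1 gave 0 calls by limma. EdgeR called 5 genes (3 higher, 2 lower) and DESeq2 72 (49 higher, 23 lower). ALDOC lost its call without mutant A (0.206) or vehicle B (0.0698). It also lost it with median centring (0.121), with edgeR (0.0726) and with edgeR on DESeq2's size factors (0.107), at log2 fold changes of -1.94 to -1.95 in the last 3. Among other settings MYBPC2 lost its call with no filter (0.122), a pseudocount of 0.1 (0.0904), only the 2 groups (0.0503) and edgeR on library totals (0.0535). COL5A1 did so with no filter (0.0563), a filter at a mean of 5 (0.0623), only the 2 groups (0.0503) and edgeR on library totals (0.0559). With the replicate letter as a block MYBPC2 (0.0565), LOC101448202 (0.0528) and COL5A1 (0.0645) lost their calls. MYBPC2 lost its call without mutant A (0.700), vehicle A (0.108), B (0.295), C (0.142) or induced wild type A (0.189). COL5A1 lost its call without mutant A (0.700), mutant B (0.311), vehicle B (0.411), vehicle C (0.156) or induced wild type A (0.242), and LOC101448202 without the same libraries (0.586, 0.138, 0.295, 0.142 and 0.155). The count was 0 without mutant A, 0 without vehicle B, 1 without vehicle C, 1 without induced wild type A and 13 without induced wild type B. For new RNA it was 0 without mutant A, vehicle A, vehicle C or induced wild type A, 1 without mutant B or vehicle B, 2 without induced wild type C and 16 without induced wild type B.

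Among the gene lists in all reads, glycolysis genes fell (median -0.31, 19 of 22 below 0, adjusted p = 4.89e-09), with ENO1 at -0.60 (SE 0.21), TPI1 at -0.71 (SE 0.24) and ENO2 at -0.70 (SE 0.23) beside ALDOC. With an estimated correlation the adjusted p was 0.0370, and 0.0674 when ALDOC was left out. That call was lost without any one library (0.0755 to 0.155: mutant A 0.0943, mutant B 0.0755, vehicle A 0.115, B 0.0756 and C 0.145, induced wild type A 0.106, B 0.148 and C 0.155). Replication-dependent histone genes rose (median 0.36, 8 of 8 above 0, adjusted p = 2.80e-04, 0.158 with an estimated correlation), with HIST1H1E at 0.71 (SE 0.23) and HIST1H1B at 0.66 (SE 0.28), at mean levels of 3.43 CPM or less for these members. Ribosomal protein genes fell (median -0.27, 34 of 34, adjusted p = 3.66e-07), and p53 targets (0.23, 19 of 22 above 0, 3.74e-04) and unfolded protein response genes (0.10, 13 of 19, 0.0397) rose, each with an adjusted p of 0.867 with an estimated correlation. The p53 genes did not move as one: the cell-cycle inhibitor CDKN1A stood at 0.54 and the cyclin CCNG1 at -0.57. Without mutant A the adjusted p was 0.736 for ribosomal proteins and 0.0520 for p53 targets, without vehicle A 0.815 for ribosomal proteins, and the unfolded protein response call was lost without mutant B (0.363), vehicle B (0.0505) and vehicle C (0.0696). The number of lists was 9 without mutant A and 11 without vehicle A.

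**Figure D2:**
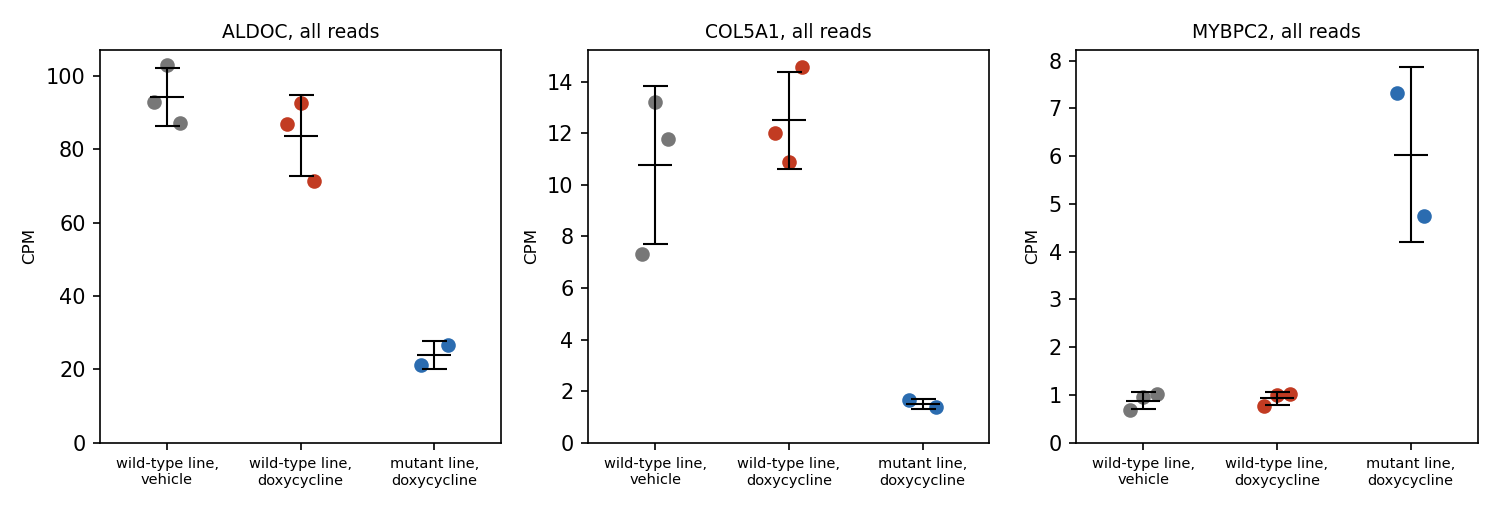
All-read CPM of ALDOC, COL5A1 and MYBPC2 per library, with points for libraries and bars for the mean and SD of the vehicle (n = 3), induced wild-type (n = 3) and induced mutant (n = 2) groups. ALDOC averaged 24.0 CPM in the induced mutant against 94.4 with vehicle and 83.8 in induced wild type, and MYBPC2 averaged 6.04 CPM against 0.88 and 0.93.

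Induced wild type was set against induced mutant to ask what differs between the 2 forms of HMGN1 when both lines receive doxycycline. The form of HMGN1 and the line differ together here and cannot be told apart. In all reads ALDOC was higher in the wild-type line by 1.76 (log2, SE 0.17; 83.8 ± 11.0, n = 3, against 24.0 ± 3.82 CPM, n = 2; limma adjusted p = 0.0159), COL5A1 by 2.42 (SE 0.29, adjusted p = 0.0278) and LOC101448202 by 2.34 (SE 0.25, adjusted p = 0.0159). MYBPC2 was lower (-1.85, SE 0.23, adjusted p = 0.0382). Small p in all reads, not passing, also belonged to C8orf73 (1.37) and the receptor phosphatase gene PTPRF (1.33) among higher genes and to ANKRD30BL (-1.65), MIR663B (-1.07) and SORCS2 (-1.01) among lower ones (adjusted p from 0.628 to 1.00). In converted reads no gene passed. IL6R was listed at 0 in both mutant libraries and at 3.33, 7.80 and 4.72 FPKM in induced wild type A, B and C (adjusted p = 0.148). The peroxisomal thiolase gene ACAA1 (1.26), the helicase gene RECQL4 (1.59), FAM69B (1.26) and the endosomal sorting gene HGS (1.33) had the smallest p among higher genes, and ANKRD30BL (-1.69), FAM53B (-1.50), the phosphodiesterase gene PDE3A (-0.99), ZMIZ1 (-1.31) and ZC3H3 (-1.18) among lower ones. Limma called 0 of 5737 genes in converted reads (169 at an unadjusted p under 0.05) and 0 of 9653 in new RNA (287), against 4 of 12458 in all reads, where edgeR called 3 and DESeq2 14. ALDOC was not among the 3 of edgeR (adjusted p = 0.322). It also lost its call with edgeR on DESeq2's size factors (0.358) and with median centring (0.355), at log2 fold changes of 1.63 to 1.67. MYBPC2 lost its call with no filter (0.216), a pseudocount of 0.1 (0.115), only the 2 groups (0.186) and edgeR on library totals (0.0670). It also lost it with the replicate letter as a block (0.0509). The groups did not overlap for 676 converted-read genes higher and 297 lower, 17.0% against 20% by chance. In all reads they did not overlap for 1643 higher and 224 lower, and in new RNA for 9.86%. With depth as a covariate IL6R and ANKRD30BL passed in converted reads (adjusted p = 0.0029 each). IL6R also passed with a pseudocount of 0.1 (0.0202) and with only the 2 groups (0.0487). Leaving out vehicle A gave 1 converted-read call and leaving out induced wild type B gave 3, and 1 in new RNA. The all-read count was 0 without mutant A, mutant B, vehicle B, induced wild type A or induced wild type B, and 2 without vehicle C or induced wild type C. In those 5 settings ALDOC had an adjusted p of 0.403, 0.0537, 0.0543, 0.215 and 0.0543 in that order and LOC101448202 of 0.403, 0.148, 0.0672, 0.237 and 0.0543, and COL5A1 (0.0619 and 0.0627) and MYBPC2 (0.0989 and 0.0788) also lost their calls without vehicle C and induced wild type C.

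Of the gene lists in all reads, glycolysis genes stood higher in induced wild type than in induced mutant (median 0.30, 21 of 22 above 0, adjusted p = 6.06e-08), including PGK1 (0.47, SE 0.14), ENO2 (0.66) and PFKFB4 (0.61). Replication-dependent histone genes stood lower (median -0.32, 8 of 8 below 0, adjusted p = 1.26e-09), including HIST1H1E (-0.64, SE 0.23). With an estimated correlation both kept an adjusted p of 0.0270. Without ALDOC the glycolysis value was 0.0569. Both of these calls were lost without each library other than mutant B, with 0.208 for both without mutant A, and for glycolysis and histones in turn 0.103 and 0.106 without vehicle A, 0.0778 for both without B, 0.102 for both without C, 0.0776 for both without induced wild type A, 0.425 and 0.122 without B, and 0.146 and 0.158 without C. G2/M genes stood higher (median 0.36 against 0.12 for all genes, 23 of 24 above 0, adjusted p = 8.94e-04), including the mitotic genes ASPM (0.84, SE 0.36) and TOP2A (0.76, SE 0.38), with an adjusted p of 0.956 with an estimated correlation. Mitochondrial ribosome (median -0.08, adjusted p = 2.65e-07), oxidative phosphorylation (-0.08, 3.57e-06), heat shock (-0.12, 1.06e-05), p53 target (-0.03, 0.0045) and unfolded protein response genes (-0.07, 0.0045) stood lower relative to other genes. Their adjusted p with an estimated correlation was 0.362 for mitochondrial ribosome and heat shock genes and 0.956 for the other 3. S-phase genes (median 0.01, mean -0.01, adjusted p = 0.0105) and MYC and ribosome biogenesis genes (median 0.04, mean 0.05, 0.0481), each with an adjusted p of 0.956 with an estimated correlation, were below the median of all genes while their own medians lay above 0, and under median centring, quantile normalization and edgeR's scaling those medians lay below 0 (-0.12, -0.07 and -0.14 for S phase, -0.09, -0.08 and -0.11 for MYC). Those 3 scalings put the median of all genes at -0.02, -0.01 and -0.01. Without mutant B the calls of G2/M (0.136), mitochondrial ribosome (0.385), oxidative phosphorylation (0.501), MYC (0.905), S-phase (0.121) and unfolded protein response genes (0.136) were lost. Without induced wild type B those of p53 targets (0.466), S-phase (0.0729), unfolded protein response (0.0729) and MYC genes (0.0977) were lost, without C those of oxidative phosphorylation (0.549) and MYC (0.188), without mutant A that of p53 targets (0.531), and MYC also without vehicle A (0.121), B (0.0622) and C (0.0612). In converted reads none of 21 lists passed, and the smallest adjusted p was 0.346.

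The genes with the highest converted-read values with vehicle were UNC45B, a myosin chaperone (494 ± 140 FPKM), the chaperone HSPA8 (308 ± 36.3), ANKRD30BL (269 ± 39.9), the autophagy gene AMBRA1 (219 ± 123) and NUDCD3 (192 ± 27.1). SLCO5A1, CHCHD3, STMN1, GOLGA3 and LRRC75A-AS1 followed (170 to 130). These values show no trace of division by transcript length, so the order need not be that of transcript abundance. Markers of other cell types were few in all reads: of the T-cell markers 3 were measured, led by IL7R at 33.7 CPM, of the myeloid markers 3, led by CSF1R at 415 CPM, of the fibroblast and epithelial markers 1, VIM at 283 CPM, and of the erythroid markers none, with EPOR the highest at 0.377 CPM. Of the myeloid markers, CSF1R included, 0 reached the filter in converted reads and 0 in new RNA. Whether the CSF1R reads come from that gene was not tested.

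In new RNA, unfolded protein response genes rose in induced mutant against vehicle (median 0.25, adjusted p = 0.0393, 0.590 with an estimated correlation) and G2/M genes fell (-0.22, adjusted p = 0.0393, 0.674 with an estimated correlation). In induced wild type against induced mutant, heat shock genes (-0.21, 12 of 12 below 0, adjusted p = 0.0062), unfolded protein response genes (-0.20, 0.0241), p53 targets (-0.11, 0.0317) and S-phase genes (-0.08, 0.0337) stood lower and G2/M genes higher (0.21, 0.0062). With an estimated correlation the adjusted p was 0.356 for the S-phase and G2/M genes and 0.327 for the other 3. The remaining lists passed in none of the 3 comparisons in any measure. In all reads their smallest adjusted p was 0.523 for the Down syndrome critical region, 0.245 for HMG proteins, 0.297 for precursor B-cell genes, 0.0527 for histone variants and chaperones and for BCL2-family genes, 0.493 for immediate early and for polycomb genes, 0.320 for interferon-stimulated genes, 0.775 for ATF4 targets, 0.321 for cholesterol synthesis, 0.827 for NF-kB targets, 0.491 for acetylation writers and readers and 0.542 for the RNA polymerase II machinery. Mitochondrially encoded genes had no tested member, nor had HOX and other polycomb target genes, of which PAX6 was highest at 0.319 CPM.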

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

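The planned settings were fixed before the data were examined, while all settings for all reads and new RNA, median centring, depth as a covariate and leaving out libraries in the gene lists were chosen after the data were seen. Of the results that answer a comparison, 327 values under other settings were classed as kept, 90 as moved, 8 as weakened, 1 as stronger and 2 as reversed. For single genes, kept means the same direction and side of the threshold. Kept counts and levels could shift, and a kept level could change sign. Between the induced groups the difference in converted share went from 0.29 to -0.15 percentage points with the replicate block. The log2 difference in sums there was -0.045, and that in the median over genes was 0.07. Both were classed as kept, so the 2 reversed values leave out such changes of sign. Of the named genes 597 values kept direction and side, 187 weakened, 8 became stronger and 1 reversed. Where no construction is named the cause was not tested. In simulated data fewer 2-fold changes were found in converted reads than in all reads, and whether depth limits them was not tested. Lists in new RNA were not rerun without single libraries. MECOM in all reads was at -0.10, against a converted-read group listed at 0. The HMGN1 log2 fold change for induced wild type against vehicle was -0.0014 under median centring of the converted reads, and that for induced mutant against vehicle was 0.38 in all reads.

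For induced mutant against vehicle in converted reads, 93 genes were called with quantile normalization, 41 with median centring, 1 with a pseudocount of 0.1, 2 with only the 2 groups in the fit (fewer libraries) and 4 in all reads, and leaving out each library in turn gave 0 to 68. Between the induced groups the count was 1 with a pseudocount of 0.1, 1 with only the 2 groups, 4 in all reads and 0 to 3 leaving out each library. For induced wild type against vehicle it was 0 to 1 leaving out each library. In all reads, induced wild type against vehicle had 2 calls with median centring, 2 with edgeR, 2 with edgeR and DESeq2's size factors, 2 with DESeq2 and 0 without any single library. Induced mutant against vehicle had 2 with a filter at mean 5, 7 with only the 2 groups, 72 with DESeq2 and 0 to 13 leaving out each library, and the induced groups 14 with DESeq2 and 0 to 4. In new RNA, induced wild type against vehicle had 10 calls with no filter, 1 with a filter at mean 1, 1 with no centring and 1 to 2 leaving out each library. HMGN1 there was 2.08 with a filter at mean 1, 2.30 with no centring and 1.79 to 2.18 leaving out each library. Induced mutant against vehicle had 80 with no filter, 0 with a filter at mean 1, with a pseudocount of 0.5 and with no centring, 10 with only the 2 groups and 0 to 16 leaving out each library, and HMGN1 was 1.42 with no filter (adjusted p = 5.97e-04). Between the induced groups new RNA had 2 with no filter and 0 to 1.

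With depth as a covariate the converted-read counts were 1, 157 (155 higher, 2 lower) and 2 in the 3 comparisons, and new RNA between the induced groups had 1.

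Of the lists in converted reads, 0 passed with an estimated correlation and 0 with fry in both comparisons with vehicle, and leaving out each library gave 0 to 2 and 0 to 1. In all reads the lists passing were 0, 1 and 2 with an estimated correlation and 0, 1 and 1 with fry in the 3 comparisons, and 0 to 7, 5 to 11 and 6 to 11 leaving out each library. The log2 difference in summed FPKM ran from 0.12 to 0.30, 0.13 to 0.43 and -0.20 to 0.11 leaving out each library, and that in converted share from 0.23 to 1.18, -0.19 to 1.04 and -0.33 to 0.91 percentage points. HMGN1 in converted reads ran from 0.04 to 0.52, -0.64 to -0.09 and 0.43 to 0.94.

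With the replicate letter as a replicate block, 149 genes were called for induced mutant against vehicle in converted reads (147 higher, 2 lower), 1 in all reads and 7 in new RNA, and for induced wild type against vehicle 1 in all reads and 2 with edgeR. Whether the letters mark a shared batch is not known. Deviations of same-letter vehicle and induced wild-type libraries correlated across genes at 0.10, -0.10 and 0.29 in converted reads. In all reads the values were 0.29, -0.36 and 0.65, while vehicle A with induced wild type B, of different letters, stood at 0.62. Under the block HMGN1 stood at 0.34, -0.34 and 0.68 in converted reads, and no other count of calls moved by over 1.5 times. The difference in converted share became 0.87 instead of 0.42 percentage points for induced mutant against vehicle and -0.15 instead of 0.29 between the induced groups.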

Other observations

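The tests on pseudogene sequence, on transcription of the host genes, on the glycolysis list and on regrouped libraries in all reads and new RNA were chosen after the results they bear on had been seen. The other tests were written before their results. The per-library values of a few genes, mostly abundant ones, follow, as they were high in the same libraries (mutant A and B and induced wild type B). ANKRD30BL stood at 4705 and 1471 CPM in mutant A and B, 497, 527 and 546 in vehicle A, B and C, and 624, 1098 and 865 in induced wild type A, B and C. In the same order C11orf67 stood at 1692 and 941, at 287, 230 and 431, and at 545, 993 and 663 CPM, and PPEF2 at 124 and 60.2 in the mutant, 20.1 ± 5.72 with vehicle (SD, n = 3) and 32.7, 58.2 and 42.4 CPM in induced wild type. In converted reads UNC45B stood at 1993 and 1431, at 653, 390 and 438, and at 543, 2078 and 550 FPKM. SLCO5A1 stood at 612 and 588 in the mutant, 170 ± 33.1 with vehicle (SD, n = 3) and 195, 551 and 220 FPKM in induced wild type. No explanation of these values was tested.

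The converted-read calls for induced mutant against vehicle were nearly all rises, and a trend on gene span is a candidate explanation. The fold change followed gene span across the 5004 genes with a value (Spearman rho 0.50 across genes, which are not independent replicates). After each library's trend on span was removed, 10 genes were called, against 30 before on the same genes. Of the 10, 9 were among the 23 called over all tested genes. For the rises among those 23 with a span value, the median log2 fold change was 2.14 before and 1.52 after. What ended each call was not tested. A trend on GC content as the whole cause is argued against, as 53 genes were called after its removal, 19 of them among those 23 (rho -0.12). Vehicle A alone is argued against too, as 35 were called without it, though 0 were called without vehicle B, 9 without induced wild type A and 68 without vehicle C. The mutant protein, the line and doxycycline differ together here and stay open as untested explanations.

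The reads of C1orf14 and TMEM131 may come in part from induced HMGN1 transcripts placed at the HMGN1 pseudogenes inside them. These hold 44.8% (C1orf14) and 49.46% (TMEM131) of the HMGN1 coding sequence unbroken, as 25-base windows, against 24.01% for the next of 13 tested hosts, ACTN1, and a median of 0, and only those 2 hosts were higher in every induced wild-type library than in every vehicle library. In C1orf14, on the strand of its pseudogene, the conversion rate was 1.93% ± 1.39 with vehicle and 9.81% ± 2.82 in induced wild type, and in TMEM131, on the opposite strand, 5.07% ± 1.47 and 3.76% ± 0.21. Transcription of the host genes also stays open, as the TMEM131 converted-read log2 fold change was 1.40, at 5.68 ± 2.62 against 1.83 ± 1.59 FPKM. A pair of tests written beforehand came out against placement at pseudogenes. In the first, on reads, MPP1 stood at -0.12 (SE 0.14, FAM174B below the filter). In the second, 30.22 exon-crossing windows were closest to the C1orf14 and TMEM131 pseudogenes, against 126.22 for those of FAM174B and MPP1. It was then seen that the counted FAM174B and MPP1 transcripts do not span their pseudogenes, which voids the test on reads. The window counts use sequence alone, so their result still goes against placement of exon-crossing reads at the closest pseudogene. The 13 hosts were chosen at that point. They leave out FAM174B and MPP1, whose pseudogenes hold 63.44% and 49.1% of the coding windows.

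ALDOC was lower in the mutant line than in both wild-type groups, and a difference between the lines in glycolysis genes is a candidate explanation, chosen after ALDOC and PGK1 had been seen lower. The glycolysis list had a median of -0.31 against vehicle and passed in both all-read comparisons but not in converted reads (median 0.12 against vehicle, adjusted p = 0.847, and 0.804 between the induced groups) or new RNA (-0.04, 0.948 and 0.968), and in all reads without ALDOC and with an estimated correlation the adjusted p was 0.0674 and 0.0569, and with the replicate block and an estimated correlation 0.174 and 0.135. Leaving out any 1 library with an estimated correlation ended the call against vehicle (adjusted p from 0.0755 without mutant B to 0.155 without induced wild type C), and leaving out any but mutant B ended that between the induced groups (from 0.0776 without induced wild type A to 0.425 without B). The 2 comparisons share the mutant libraries and so are not independent. COL5A1 and MYBPC2 belong to no tested list, and the same dose in the wild-type line argues against doxycycline alone, with log2 fold changes of -0.18 (SE 0.16) for ALDOC, 0.23 (SE 0.26) for COL5A1 and 0.04 (SE 0.21) for MYBPC2, while the line, the mutant protein and a response to doxycycline of the mutant line stay open as untested.

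The 6 libraries of the wild-type line can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In converted reads and in all reads all 10 splits gave as many calls as the real one, which a real count of 0 fixes beforehand, and the highest of the other splits was 0, while in new RNA 1 of 10 did, the real split with 2 calls, with the highest other at 0. At an unadjusted p under 0.05 the real split had 455 genes in converted reads, 118 in all reads and 299 in new RNA, and the highest others had 770, 4002 and 1550. The first 2 of these set vehicle A and B and induced wild type B, the least deep of the 6 libraries, against the rest, but vehicle A with induced wild type A and B, which do not follow depth, also gave 3403 in all reads, so there is a structure of the samples whose cause was not tested. With depth as a covariate, chosen after these values were seen, all-read calls were 0, 4 and 4 in the 3 comparisons, the same genes as without it, and converted-read calls 1, 157 and 2 instead of 0, 23 and 0.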
